A study of Mus musculus with 6 samples.

How the data were processed

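The series holds 6 mouse samples of sorted bone marrow cells, 3 labelled inv(16)/KitD816Y L-GMP and 3 labelled wild-type GMP of the C57BL6 background. Per the labels, the marrow was fresh and untreated, RNA came from 200000 sorted cells per sample and was extracted with a miRNeasy kit, and biotin-labelled material was hybridised to Mouse Gene 1.0 ST arrays. Per the labels, the mutant cells were sorted as lineage-negative, Sca1-negative, c-Kit-positive, CD41-negative, Fc gamma receptor-positive and CD150-negative. The wild-type cells were sorted as lineage-negative, IL7R-negative, Sca1-negative, c-Kit-positive, Fc gamma receptor-high and CD34-positive. Groups and replicate numbers were taken from the sample titles. Scan dates, batches and the laboratory of each array are not given in the sources used here. The design text says that the series includes re-analysed samples of an earlier series, and it does not say whether any of the 6 arrays compared is among them.

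The deposited values are log2 expression levels per probe set, made by the authors with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. The version of RMA and the annotation it used are not given in the sources used here. The series value table was the main source. A second deposited table of log2 values covers the same 6 arrays and 18 further columns that belong to other samples. Those 18 columns were not used, and the table's 6 columns served as an alternative (correlation with the main table across probe sets 0.994 on each array). Its medians lay between 6.23 and 6.34 against 6.03 and 6.13 in the main table. RMA forces the arrays of a run toward a common distribution, so a global change in RNA content per cell cannot be seen, and it compresses differences near the background. The files used hold no probe intensities or detection calls. As a background yardstick, the 95th percentile of the values of olfactory and vomeronasal receptor genes was used, 5.57 on the log2 scale. The number of arrays, 3 per group, limits the precision.

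Probe sets were named from GEO's platform annotation, with symbols looked up through gene identifiers in a RefSeq gene table of GRCm38.p6. Of 35556 probe sets, 21789 had a single gene symbol, 1621 had several and 12146 had none. Of the single-symbol probe sets, 21698 matched the RefSeq table and 0 symbols needed an update. Probe sets with several symbols or none were left out; 143 and 2015 of them changed over 2-fold. Each gene was represented by its probe set with the highest mean over the 6 arrays, giving 19938 genes. Of 999 genes with several probe sets, 26 had probe sets past the threshold in opposite directions. A gene absent from this table was not analysed here, which applies to 3 of the genes chosen by name. No genome build is given for the files, so no coordinates are printed.

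The comparison was inv(16)/KitD816Y L-GMP minus wild-type GMP. A linear model was fitted per gene to the log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend, robust fitting or a block, two-sided, with Benjamini-Hochberg adjustment over 19938 genes and a threshold of 0.05. Genes changed over 2-fold also had a log2 change of at least 1 in size. All adjusted p-values of genes in the text come from this fit unless another is named. Errors are SD over 3 arrays for levels and the moderated SE for log2 changes. With 3 arrays against 3, an exact permutation test of a single gene cannot go below p = 0.1.

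Gene lists were fixed before the data were examined: 17 pathways, 13 sets of cell type markers and 4 sets defined by symbol patterns, 34 in all. The histone pattern was matched through older symbols in the RefSeq table. Some genes stand in 2 lists, such as Hdc (granule, mast cell), Gzmb (STAT5, mast cell), Gata2 (stem, mast cell), Flt3 (stem, monocyte) and Meis1 (Hoxa, stem). The 33 lists with at least 5 measured genes were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with the correlation estimated from the list, each adjusted over the 33 lists. The rotation test fry was run beside it. Counts of members that rose or fell use the adjustment over all genes, and the count adjusted over the list alone is given beside them.

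The rule for the genes named in the report was also fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, leaving out predicted and clone-named genes, receptors, small RNAs and antigen receptor segments. It takes from each list up to 3 risers and 3 fallers past the threshold, or the brightest member where none passed. It always takes the genes named in the genotype and their partner, the AKT genes and the sort markers. Genes named only in the closing section were chosen after their values were seen.

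The fit and the list test were tested on simulated data with the real means and spreads of the 19938 genes. For the comparison of the 2 groups the fit recovered 56% of 50 genes changed by 0.5 on the log2 scale, 90% of 50 changed by 1, and 100% of 50 changed by 2 and of 50 changed by 4. Of 178 calls 5 were unchanged genes, and limma made 0 calls where no effect was simulated. Camera called the shifted list and 0 of 20 random lists. Far fewer genes were changed in the simulation than the 10317 that changed in the data, so the recovered shares are not the power of this comparison. The simulated genes were drawn independently, so they do not check whether the preset correlation suits the real lists. Alternatives tried were the replicate number as a block, renewed quantile normalization, arrays set to a common median, cyclic loess, a filter on dim probe sets (above the array's 30th percentile on at least 3 arrays), the second processed table, each array left out in turn, eBayes with trend and robust fitting, array weights, the mean of a gene's probe sets, a test against a 2-fold bound, a limit of 4-fold, adjustment over all probe sets, and the estimated list correlation. Figures were drawn with matplotlib 3.10.9.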

Results

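Gene expression was measured in sorted bone marrow cells labelled as granulocyte-macrophage progenitors (GMPs) or as L-GMP, from mice of 2 genotypes. Wild-type GMPs give rise to neutrophils and monocytes. One group carried inv(16) together with KitD816Y and is labelled L-GMP. The inversion inv(16), found in human acute myeloid leukaemia, fuses CBFB to MYH11, and D816Y is an activating change in the kinase domain of the receptor KIT. The other group was wild-type GMP of the C57BL6 background. Each group held 3 arrays of the Mouse Gene 1.0 ST type, with RNA from 200000 sorted cells per array. The median RMA value (log2) over all 35556 probe sets lay between 6.03 and 6.13 on the 6 arrays, and the small number of arrays limits the precision. The design text places the comparison in a study of AKT activation in acute myeloid leukaemia and of the response to chemotherapy. The question was which transcripts differ between the L-GMP cells that carry both lesions and wild-type GMPs. The sources used here do not say whether the arrays of a group came from separate animals, so p-values measure only the spread between these samples. The groups were also sorted with different marker sets, so gate and genotype cannot be told apart in any value below.

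Transcripts of the sort markers showed how the 2 gates related to the RNA. Kit, the gene of the receptor named in the genotype and a marker of both gates, had a mean of 10.66 ± 0.32 (SD, n = 3) in the inv(16)/KitD816Y cells and 10.77 ± 0.06 (SD, n = 3) in the wild type, with an adjusted p of 0.543 in limma. The Fc gamma receptor genes Fcgr3 and Fcgr2b, the antigens of both gates, differed by 0.11 and -0.02 on the log2 scale (adjusted p = 0.488 and 0.887). Cd34, required in the wild-type gate alone, fell by 2.28 ± 0.09 (SE) in the mutant cells, a 4.85-fold lower level (adjusted p = 1.64e-08). Itga2b, which encodes CD41, rose by 3.22 ± 0.09 (SE), or 9.34-fold (adjusted p = 2.23e-09), although CD41-positive cells were gated out of the mutant sort. Slamf1, which encodes CD150, rose by 0.96 ± 0.19 (SE, adjusted p = 0.0018), with both group means, 5.16 and 4.20, below the background yardstick of 5.57. Il7r differed by -0.20 (adjusted p = 0.0672, past the threshold in 3 of 14 alternatives) and lay below the same yardstick in both groups. Among the genes of the fusion and its partners, Runx1, the DNA-binding partner of CBFB, rose by 1.17 ± 0.09 (SE, adjusted p = 2.79e-06). Cbfb was 0.21 ± 0.08 (SE) lower, with an adjusted p of 0.0486 that was lost in 8 of 15 alternatives (0.0652 with a replicate block, 0.139 without inv(16)/KitD816Y L-GMP replicate 2). Myh11 was at 5.89 and 5.83 (adjusted p = 0.526). Whether its probes lie in the part kept by the fusion was not analysed here, so the Myh11 value checks no label.

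**Figure D1:**
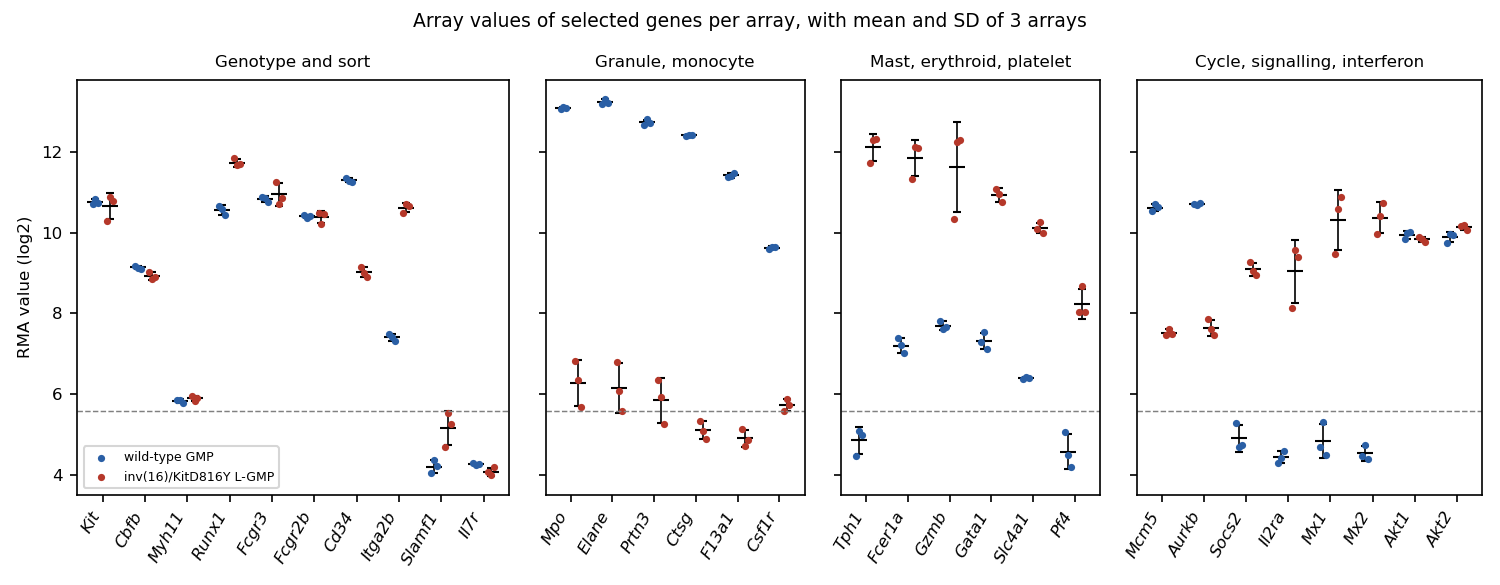
RMA values (log2, vertical axis) of selected genes on each array, as blue points for wild-type GMP and red points for inv(16)/KitD816Y L-GMP, with black bars for the mean and SD of 3 arrays. The dashed line is the background yardstick of 5.57. Kit and Akt1 overlap between the groups, Mpo and Elane lie near 13 in the wild type and near 6 in the mutant cells, and Tph1 and Mx2 show the opposite order.

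Of 19938 genes tested, 10317 changed at an adjusted p under 0.05, 4150 higher and 6167 lower in the inv(16)/KitD816Y cells. The size of the excess of lower genes depended on the scaling. It was 3792 higher and 8100 lower after renewed quantile normalization, and 4230 higher and 5750 lower with cyclic loess. A change of over 2-fold was found for 2867 genes (1381 higher, 1486 lower), and 992 of them changed over 4-fold. When the test itself required a change beyond 2-fold, 1867 genes remained. The groups did not overlap for 12234 genes, or 61.4%, where chance gives 10%. In 696 of the genes changed over 2-fold the lower group lay at background, so their lower level was not measured and the size of their change depends on the floor of the probe set. Among the genes named here this holds for 47: Tph1, Cd55b, Clca3a1, Il6, Ano3, Cd200r4, Clca3a2, Mx2, Ctsg, Emb, Atp8b4, Gria3, F13a1, Parp8, Adgrl4, Inpp4b, Pik3r3, Phlda1, Dusp4, Spry2, Il2ra, Socs2, Zmat3, Fas, Mx1, Iigp1, H2-Ab1, H2-Aa, Hoxa5, Cd27, Flt3, Anxa1, Cxcr2, Adgre1, Pf4, Cd9, Cd200r3, Mcpt8, Prg2, Epx, Ear6, Emcn, Olfr857, Vmn2r96, Olfr920, Mir687 and Mir186. Pairs of arrays correlated across genes at 0.993 to 0.997 within a group and at 0.903 to 0.905 between groups, genes not being independent replicates. Within the mutant group, inv(16)/KitD816Y L-GMP replicate 1 correlated at 0.993 with each of the others, which correlated at 0.996 with each other. The group means of Hoxa5, Cd5l, Fcrla, Rag2, Dntt, Cd28, Fabp4, Emcn, Olfr714, Mir181b-2, Slamf1 and Il7r lay under the background yardstick in both groups, so the sizes of their differences have no measured level on either side.

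Of the 10 genes with the largest fitted rises 8 lay at background in the wild type, and of the 10 with the largest fitted falls 7 lay at background in the mutant cells, so the order within these sets is not a measured one. The value of Tph1, the enzyme that starts serotonin synthesis outside the brain, rose by 7.28 ± 0.19 (SE) on the log2 scale, from background to 12.13. Cd55b and Cd55, which encode complement decay-accelerating factors, rose by 7.21 and 6.05. The chloride channel accessory genes Clca3a1 and Clca3a2 rose by 6.61 and 5.90, and the cytokine gene Il6 by 6.18 ± 0.10 (SE), from background to 10.33. The remaining genes among the 10 largest rises were Ano3, Cd200r4, the interferon-induced GTPase gene Mx2 and the p53 target Perp, each between 5.85 and 6.16. Among the 10 largest falls, Elane (-7.11 ± 0.24, SE), Prtn3 (-6.89) and Mpo (-6.81) had a mutant group mean above background. On inv(16)/KitD816Y L-GMP replicate 3 they were at 5.57, 5.26 and 5.68, so Prtn3 lay below the yardstick of 5.57 there and the others close to it. Ctsg (-7.32 ± 0.11, SE), Emb (-7.26), Atp8b4 (-6.89), Gria3, F13a1, Parp8 and Adgrl4 (the last 4 between -6.68 and -6.45) had a mutant group mean at background. The highest adjusted p among these 20 genes was 7.58e-09, that of Elane.

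Neutrophil granule genes were the most strongly reduced of the lists fixed before the data were examined. Ctsg, Elane and Prtn3 encode the serine proteases of the primary granule and Mpo its peroxidase. Elane went from 13.26 ± 0.06 (SD, n = 3) in wild-type GMPs to 6.15 ± 0.62 (SD, n = 3), a 138-fold lower level, and Mpo from 13.09 ± 0.03 to 6.28 ± 0.57 (SD, n = 3), a 112-fold lower level. Both mutant means lay not far above the background yardstick of 5.57, near which differences are compressed. Of 15 measured genes of the primary granule and early neutrophil list, 12 fell and 3 rose, with a median log2 change of -2.90 (15 changed adjusted over the list alone). The 3 that rose were Hdc (0.49), Ctsc (0.30) and Srgn (0.23), of which Ctsc and Srgn lost their calls in several alternative settings. The list stood below the other genes in limma's camera test (adjusted p = 1.46e-05), with adjusted p = 0.131 with an estimated correlation. Late neutrophil genes fell in 9 of 16 cases, rose in 1 (Mmp9, 0.40) and did not pass in 6 (10 changed adjusted over the list alone). The falls included Anxa1 (-4.61), the chemokine receptor gene Cxcr2 (-3.16) and S100a8 (-2.47). That list had an adjusted p of 0.0269 and an adjusted p = 0.54 with an estimated correlation, and it missed the threshold after renewed quantile normalization (0.0547), without dim probe sets (0.101), without inv(16)/KitD816Y L-GMP replicate 1 (0.0506) and without wild-type GMP replicate 2 (0.0791).

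Monocyte and dendritic cell genes fell in 13 of 17 cases, with 1 rise and 3 that did not pass (15 changed adjusted over the list alone). F13a1 fell by 6.53 ± 0.11 (SE), Ly86 by 5.34 ± 0.10 (SE), and Csf1r, the receptor for the growth factor of macrophages, by 3.91 ± 0.09 (SE). The gene that rose was the high-affinity Fc gamma receptor gene Fcgr1, by 1.94. The list's median was -1.18 (camera adjusted p = 3.21e-05; adjusted p = 0.213 with an estimated correlation). Eosinophil genes fell in 7 of 8 cases (7 adjusted over the list alone), among them the granule protein genes Prg2 (-4.38), Epx (-4.09) and Ear6 (-2.59). Their list had a median of -1.39 (adjusted p = 0.00428; adjusted p = 0.216 with an estimated correlation).

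Genes of mast cells and basophils, erythroid cells and megakaryocytes moved the other way. In the mast cell and basophil list 11 of 16 genes rose, 2 fell and 3 did not pass (13 changed adjusted over the list alone), with a median of 1.48 (adjusted p = 4.91e-05; adjusted p = 0.213 with an estimated correlation). Cd200r3 rose by 5.47 ± 0.15 (SE), Fcer1a, the alpha chain of the high-affinity IgE receptor, by 4.66 ± 0.20 (SE) or 25.2-fold, and the granzyme gene Gzmb by 3.93 ± 0.43 (SE). Gzmb was at 10.34 on inv(16)/KitD816Y L-GMP replicate 1 and at 12.26 and 12.29 on the other mutant arrays, against a wild-type mean of 7.70. The basophil protease gene Mcpt8 fell by 4.34 ± 0.13 (SE), so members of this list did not move as one. Gata2, also a stem cell marker, was 0.25 lower with an adjusted p of 0.044, a call that 9 of 15 alternatives ended, among them the study's second processed table (-0.09, adjusted p = 0.454). Of 15 erythroid genes 13 rose, 1 fell (Tfr2, -0.41) and 1 did not pass (14 changed adjusted over the list alone). The metallothionein gene Mt2 rose by 4.61, the anion exchanger gene Slc4a1 by 3.71 and Gata1, the erythroid and megakaryocytic transcription factor, by 3.62 ± 0.12 (SE), or 12.3-fold. The erythroid list had a median of 2.35 (adjusted p = 2.94e-09; adjusted p = 0.116 with an estimated correlation). In the megakaryocyte and platelet list 7 of 12 genes rose, 1 fell and 4 did not pass (10 changed adjusted over the list alone). F2rl2 rose by 4.09, Gp5 by 3.92 and the platelet factor gene Pf4 by 3.67, while Cd9 fell by 2.62. Its median was 0.47 (adjusted p = 0.00683; adjusted p = 0.212 with an estimated correlation).

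Genes of the cell cycle were lower in the mutant cells. All 23 measured DNA replication genes fell, each by over 2-fold, with a median of -2.31. Mcm5 fell by 3.11 ± 0.09 (SE), Cdc45 by 3.03 ± 0.09 (SE) and Mcm3 by 2.97 ± 0.13 (SE). The list had a camera adjusted p of 9.41e-14 and an adjusted p = 0.0802 with an estimated correlation, and 23 genes changed adjusted over the list alone. Of 21 mitosis genes 20 fell and 1 did not pass (20 adjusted over the list alone), including the kinase gene Aurkb (-3.07), Top2a (-2.99, or -1.66 with the mean of its 2 probe sets) and the checkpoint kinase gene Bub1 (-2.91). Their median was -1.88 (adjusted p = 1.45e-07; adjusted p = 0.424 with an estimated correlation). That same inv(16)/KitD816Y L-GMP replicate 1 had a Bub1 value of 7.29, against 5.92 and 6.08 on the other mutant arrays, and without it the median of the mitosis list was -2.17 (adjusted p = 6.72e-12). Replication-dependent histone genes fell in 24 of 31 cases, rose in 3 and did not pass in 4 (29 changed adjusted over the list alone). H2ac4 fell by 4.02, H1f1 by 3.50 and H1f5 by 3.39, while H1f2, H2bc4 and H2bc21 rose by 2.04, 1.67 and 0.85. Their list had a median of -1.80 (adjusted p = 2.25e-07; adjusted p = 0.116 with an estimated correlation). The genes of MYC and ribosome biogenesis changed less, with 12 of 20 lower and 8 that did not pass (12 adjusted over the list alone) and a median of -0.38. Nolc1 fell by 0.85, Myc by 0.84 ± 0.11 (SE) and Nop16 by 0.78. That list had an adjusted p of 0.0276 and an adjusted p = 0.54 with an estimated correlation, and it missed the threshold after renewed quantile normalization (0.0743), without dim probe sets (0.058) and without inv(16)/KitD816Y L-GMP replicate 1 (0.0767).

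Among the lists of signalling, genes induced by STAT5, a transcription factor downstream of cytokine receptors and KIT, rose in 12 of 13 cases (12 adjusted over the list alone). Il2ra rose by 4.62 ± 0.31 (SE), Socs2, a feedback inhibitor of cytokine receptors, by 4.19 ± 0.16 (SE, 2.48 with the mean of its 2 probe sets), and Gzmb, which the mast cell list also holds, by 3.93. The list's median was 1.92 (adjusted p = 1.79e-08; adjusted p = 0.108 with an estimated correlation). Genes induced by the kinase ERK rose in 10 of 15 cases, fell in 2 and did not pass in 3 (14 changed adjusted over the list alone). Phlda1 rose by 4.35, Ier3 by 2.49 and the phosphatase gene Dusp4 by 2.33, while the feedback inhibitor gene Spry2 fell by 1.52 and Ccnd1 by 1.29. This list had a median of 0.66 (adjusted p = 0.00166; adjusted p = 0.116 with an estimated correlation).

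The components of the PI3K-AKT-mTOR pathway went both ways. Of 29 measured genes 12 rose, 9 fell and 8 did not pass (21 changed adjusted over the list alone), and the list was not shifted (median 0.07, adjusted p = 0.0928). Inpp4b, a phosphatase of phosphoinositides, rose by 5.11 ± 0.11 (SE) and Pik3r3, a regulatory subunit of PI3K, by 4.48 ± 0.16 (SE), both from background in the wild type, and Rictor, a subunit of mTORC2, by 1.56 ± 0.08 (SE). The largest falls were those of the adaptor gene Pik3ap1 (-2.31) and the regulatory subunit genes Pik3r5 (-2.24) and Pik3r2 (-0.94). Akt1 was at 9.84 ± 0.07 (SD, n = 3) and 9.95 ± 0.10 (SD, n = 3), a difference of -0.11 (adjusted p = 0.307). Akt2 was 0.24 higher with an adjusted p of 0.0404, a call that 10 of 15 alternatives ended (0.0596 with a replicate block, 0.227 in the study's second processed table). RNA levels do not measure the phosphorylation of AKT. FOXO-induced genes, which active AKT is known to restrain, rose in 6 and fell in 8 of 20 cases (15 changed adjusted over the list alone), with a median of -0.22 and an adjusted p of 0.908. The mean of that list was -0.03, and camera placed it above the other genes, opposite in sign to its median. Txnip rose by 2.15 ± 0.08 (SE), Irs2 by 1.01 and Cited2 by 0.88, while Pik3ip1 fell by 1.34, Sesn3 by 0.90 and Bcl6 by 0.85.

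Metabolic lists were not shifted. In the glycolysis list 7 of 16 genes rose and 5 fell (12 changed adjusted over the list alone; adjusted p = 0.179), with the glucose transporter genes Slc2a3 (3.54 ± 0.15, SE) and Slc2a1 (1.45) and the lactate transporter gene Slc16a3 (1.64) higher and the enzyme genes Pfkfb3 (-1.02), Hk2 (-0.95) and Pgam1 (-0.81) lower. Sterol and fatty acid synthesis genes rose in 8 and fell in 4 of 24 cases (12 adjusted over the list alone; adjusted p = 0.214). Lss, Fdft1 and Fads2 rose by 1.91, 1.88 and 1.42, while Fdps, Fasn and Acaca fell by 1.12, 0.86 and 0.76. Genes of ATF4 and amino acid supply rose in 9 and fell in 5 of 21 cases (14 adjusted over the list alone), with an adjusted p of 0.0798 that became 0.0458 without inv(16)/KitD816Y L-GMP replicate 1 and 0.536 with an estimated correlation. Sesn2, Asns and Ddit3 rose by 3.01, 2.00 and 1.82, while Phgdh, Pck2 and Shmt2 fell by 1.26, 1.14 and 0.83. The median of the ATF4 list was 0.00 and that of the glycolysis list -0.02, although camera placed both above the other genes. Nuclear-encoded oxidative phosphorylation genes fell in 14 and rose in 3 of 29 cases (19 changed adjusted over the list alone; adjusted p = 0.167), none by over 2-fold. Ndufa2, Uqcrc1 and Cyc1 fell by 0.98, 0.96 and 0.93, Sdhb rose by 0.98, and the rises of Atp5o (0.26, or 0.56 in the study's second processed table) and Ndufs1 (0.22) were lost in several alternative settings.

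Interferon-stimulated genes rose in 21 of 23 cases, 20 of them by over 2-fold, and 2 did not pass (21 adjusted over the list alone). Mx2 rose by 5.85 ± 0.18 (SE), its relative Mx1 by 5.49 ± 0.33 (SE) and the GTPase gene Iigp1 by 5.29 ± 0.15 (SE). The list's median was 3.09, the highest of all lists tested (adjusted p = 5.35e-17; adjusted p = 0.16 with an estimated correlation). Genes induced by p53 rose in 14 of 18 cases, fell in 2 and did not pass in 2 (16 changed adjusted over the list alone). Perp rose by 5.85 ± 0.17 (SE), Zmat3 by 5.11 ± 0.12 (SE) and the death receptor gene Fas by 3.84 ± 0.10 (SE). The 2 that fell were Pmaip1 (-0.42) and Tnfrsf10b (-0.35), whose calls were both lost in the study's second processed table. The p53 list had a median of 1.75 (adjusted p = 5.15e-09; adjusted p = 0.0802 with an estimated correlation). In the BCL2 family 4 of 14 genes rose and 5 fell (9 adjusted over the list alone; adjusted p = 0.478). Bcl2, which blocks apoptosis, fell by 1.79 ± 0.15 (SE) and Bid by 0.41, while Bcl2l1, also an inhibitor of apoptosis, rose by 1.92 ± 0.15 (SE), Bbc3 by 1.00 and Mcl1 by 0.76. The median of this list was -0.02, with camera in the other direction. Immediate-early and heat-shock genes rose in 7 and fell in 4 of 18 cases (12 changed adjusted over the list alone; adjusted p = 0.179). Egr1, Atf3 and Zfp36 rose by 2.79, 1.54 and 0.99, and Hsph1, Fos and Hspa1a fell by 0.96, 0.93 and 0.82.

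**Figure D2:**
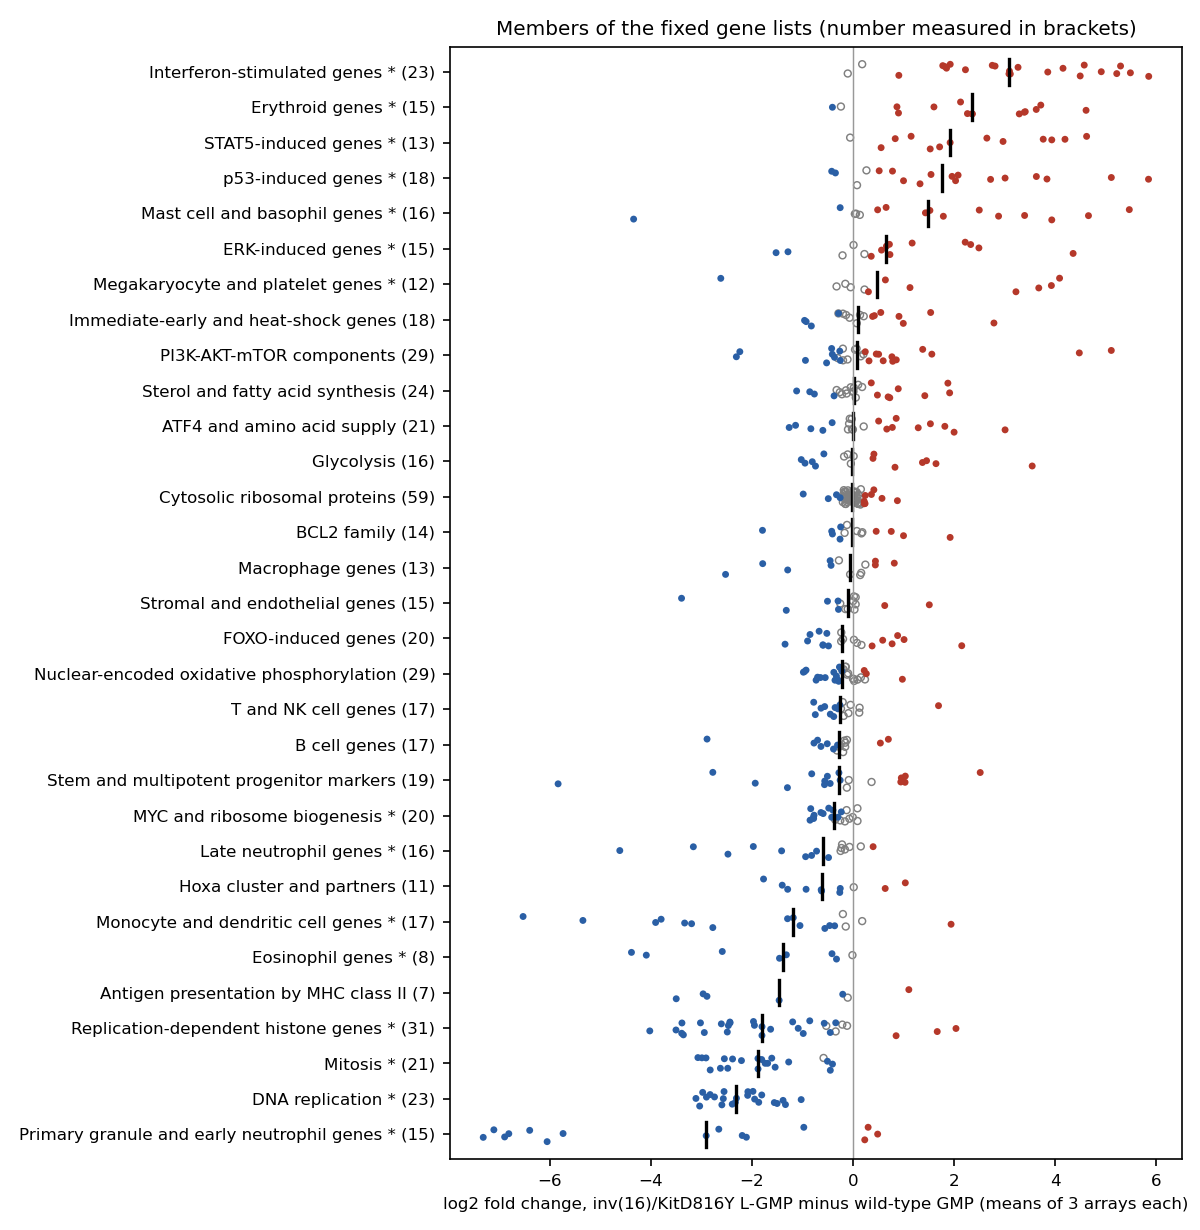
Log2 fold change (horizontal axis, inv(16)/KitD816Y L-GMP minus wild-type GMP, means of 3 arrays each) of each measured member of the fixed gene lists (vertical axis, ordered by median), with red and blue points for genes higher and lower at an adjusted p under 0.05, open grey points for the others, and black bars for medians. Stars mark the lists with a camera adjusted p under 0.05 at the preset correlation, 15 in all (0 with an estimated correlation), from the primary granule list with a median of -2.90 to the interferon list with a median of 3.09.

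Stem and multipotent progenitor markers fell in 11 and rose in 5 of 19 cases (16 adjusted over the list alone; adjusted p = 0.374). Cd27 fell by 5.83 ± 0.12 (SE), with the receptor gene Flt3 (-2.77) and Erg (-1.93) also lower, while Mllt3 rose by 2.52, Meis1 by 1.03 and Angpt1 by 1.03. Hoxa genes and their partners fell in 8 of 11 cases and rose in 2 (10 adjusted over the list alone; adjusted p = 0.109), with Hoxa9 lower by 1.77 ± 0.11 (SE), Hoxa5 by 1.40 and Hoxa7 by 1.29, and Meis1 and Pbx3 (0.64) higher. Genes of antigen presentation by MHC class II fell in 5 of 7 cases (6 changed adjusted over the list alone). H2-Ab1 fell by 3.50, H2-Aa by 2.97 and H2-DMa by 2.89, whereas H2-Eb1 rose by 1.10. The adjusted p of this list was 0.059, which became 0.0499 with a replicate block, 0.0489 without wild-type GMP replicate 3 and 0.536 with an estimated correlation.

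Lists of further cell types, which lineage-negative, c-Kit-positive gates are meant to remove, were not shifted. B cell genes fell in 7 and rose in 2 of 17 cases (10 adjusted over the list alone; adjusted p = 0.0867), with Cd79b lower by 2.89, Rag2 and Dntt lower by 0.77 and 0.70, and Fcrla and Blnk 0.70 and 0.54 higher (Blnk 0.33 in the study's second processed table). T and NK cell genes fell in 9 and rose in 1 of 17 cases (10 adjusted over the list alone; adjusted p = 0.167). Cd28, Il2rb and Thy1 fell by 0.78, 0.75 and 0.63, and Ncr1 rose by 1.69. Macrophage genes fell in 5 and rose in 3 of 13 cases (8 adjusted over the list alone; adjusted p = 0.635). Vcam1, Adgre1 and Slc40a1 fell by 2.52, 1.79 and 1.29, while Hmox1, Cd5l and Axl rose by 0.82, 0.44 and 0.44, the Cd5l call being lost when any of 4 arrays was left out. Stromal and endothelial genes fell in 5 and rose in 2 of 15 cases (7 adjusted over the list alone; adjusted p = 0.528), with Pecam1 lower by 3.39, Emcn by 1.32 and Bgn by 0.51, and Pdgfrb and Fabp4 higher by 1.51 and 0.63. Xist, transcribed from the inactive X chromosome of females, was at 11.43 ± 0.17 and 11.23 ± 0.19 (SD, n = 3 each; adjusted p = 0.173), and 0 of the 4 measured genes of the list of Xist and Y-linked genes changed in limma, with 0 at an unadjusted p under 0.05.

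Of 59 cytosolic ribosomal protein genes 8 rose, 4 fell and 47 did not pass, none over 2-fold (6 changed adjusted over the list alone; adjusted p = 0.374). Rps27l, a p53-regulated relative of a ribosomal protein gene, rose by 0.88, Rps3a1 by 0.57 and Rpl9 by 0.41, while Rps4l fell by 0.99, Rpl7l1 by 0.49 and Rps21 by 0.33. The median of this list was -0.02, with camera in the other direction. Small nucleolar and microRNA genes rose in 73 and fell in 59 of 345 cases (115 changed adjusted over the list alone; adjusted p = 0.0754), with Mir687, Mir142 and Mir186 higher by 2.75, 2.66 and 1.96 and Snora52, Snora16a and Mir181b-2 lower by 1.05, 0.84 and 0.77. Olfactory and vomeronasal receptor genes, which bone marrow cells have no known use for, changed in 128 of 1196 cases, or 10.7%, with 59 higher and 69 lower (13 changed adjusted over the list alone; adjusted p = 0.214 for the list). Olfr857 rose by 4.12, Vmn2r96 by 3.35 and Olfr920 by 1.98, and Olfr767, Olfr605 and Olfr714 fell by 0.87, 0.82 and 0.58. Over 2-fold, 6 receptor genes changed, all of them higher. The receptor count rests on the scaling and on single arrays. It was 283 (25 higher, 258 lower) after renewed quantile normalization and 171 (38 higher, 133 lower) with the arrays set to a common median. It was 83 without wild-type GMP replicate 1 and 85 without wild-type GMP replicate 3.

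Of the 33 lists tested, 15 were shifted with camera's preset correlation, 7 up and 8 down, and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05. The rotation test fry compares a list with no other genes. At an adjusted p under 0.05, fry found 28 lists moving on balance in 1 direction and 33 changed in either direction. With 10317 of 19938 genes changed, such a test passes nearly any list, so the 33 single out none. They include the olfactory and vomeronasal receptor list and the ribosomal protein list. The 28 include lists that camera did not shift, such as the PI3K-AKT-mTOR, macrophage and B cell lists. Lists called shifted or not shifted in this report rest on camera alone.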

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

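The background correction was not varied, since the files used hold no probe intensities. The count of genes changed stayed within 1.5 times the reported 10317 under all alternatives run for it, and that of genes changed over 2-fold within 1.5 times of 2867 except under stricter limits: 1867 with a test against a 2-fold bound and 992 with a limit of 4-fold, where the alternative's own construction removes genes. The number of lists shifted was 13 to 16 under other settings and 0 with an estimated correlation. A higher correlation between members does not explain that loss for every list. The ERK list had an estimated correlation of -0.0364, below the preset 0.01, yet its unadjusted camera p rose from 0.000555 to 0.0211. The p53 list had an estimated correlation of 0.0166, near the preset, and its unadjusted camera p rose from 6.24e-10 to 0.0041. For these lists the 2 forms of the test thus differ in more than the correlation. The 0 lists shifted with an estimated correlation therefore do not show that correlation between members undoes the shifts. What else in the second form of the test caused the loss was not tested. The MYC and late neutrophil lists were lost in 3 and 4 further alternatives, and no list or named gene past the threshold turned its direction. The receptor genes changed were 40 without dim probe sets, which removes most receptor genes. They were 283 after renewed quantile normalization, where 8.8% of the calls were higher against 46.1% in the reported fit. Setting the arrays to a common median, a shift of whole arrays alone, also gave mostly lower calls (38 higher, 133 lower). Such a shift can thus give this direction, and whether it accounts for all 283 calls was not tested. The median of all genes moved from -0.09 to between -0.17 and -0.08 across scalings. It was -0.17 with renewed quantile normalization (3792 genes higher, 8100 lower), -0.15 with a common median (3726 higher, 7449 lower) and -0.08 with cyclic loess (4230 higher, 5750 lower). With each array left out in turn, genes changed ranged from 8868 to 10201, genes changed over 2-fold from 2862 to 2900, lists shifted from 14 to 16, and receptor genes changed from 83 (without wild-type GMP replicate 1) to 143. No shared effect of the replicate number was seen: deviations of arrays with the same number correlated across genes at -0.01, 0.04 and 0.03. Such values cannot tell whether samples with the same number were paired by animal or handling. With the replicate number as a block, 9878 genes changed, 2868 over 2-fold, 16 lists were shifted and 111 receptor genes changed. Of 186 named genes, 13 changed their side of the threshold in at least 1 alternative. Changes near the background yardstick of 5.57 are limited by signal, which concerns 696 of the genes changed over 2-fold.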

Other observations

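Tests on cell admixture, on bright genes, on the gates, on transcripts of macrophages and plasmacytoid dendritic cells and on the strain were chosen only after the values they rest on were seen, as were all genes named in this part that the report does not name. Receptors and ligands of cytokines differed widely. Csf2rb2, the beta chain of the mouse receptor for IL-3, and Csf2rb, the beta chain shared with the receptors for IL-5 and GM-CSF, rose by 4.77 ± 0.08 and 3.05 ± 0.08 (SE, n = 3 per group), to 12.48 and 12.84. The receptor genes Il9r and Il4ra rose by 3.66 and 1.79, and the ligand genes Lif, Il4 and Il13 by 2.98, 2.74 and 2.06. Other receptor genes fell, Csf3r by 4.60 ± 0.10 (SE), Tnfrsf1a by 4.67, Cxcr4 by 4.48, Il6ra by 3.12, Il6st by 3.09 and Csf2ra by 2.01. Il6 was thus among the largest rises while both chains of its receptor were lower. The family as a whole did not shift in 1 direction. Of 162 ligand and receptor genes matched by symbol after the values were seen, 36 rose and 51 fell, with a camera p of 0.701. Over 2-fold, 26 rose and 23 fell, where 14.38% of all genes tested changed by that much. Camera does not test for change in both directions.

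Some transcription factors and regulators outside the fixed lists also differed. Cebpa, needed for granulocytes, fell by 2.84 ± 0.10 (SE) and Spi1 fell by 0.69. Irf8, needed for monocytes and dendritic cells and already counted in their list, fell by 3.80 ± 0.08 (SE). Gata3, Gfi1b and Zfpm1, a cofactor of GATA1, rose by 3.40, 2.45 and 1.74. The inhibitor genes of the cell cycle Cdkn2a and Cdkn2b rose by 4.70 ± 0.12 and 3.59 ± 0.14 (SE), beside the fall of the replication genes. Cd274 and Pdcd1lg2, which encode ligands of the checkpoint receptor PD-1, rose by 3.08 and 5.60, and Cd80 and Havcr2 by 4.48 and 3.60. Runx1t1 rose by 5.10 ± 0.20 (SE) and the X-linked tumour antigen gene Trap1a by 5.13. For Lif, Il4, Csf3r, Gata3, Pdcd1lg2, Cd80, Runx1t1 and Trap1a the lower group lay at background, so the size of the change has no measured lower level.

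In the first pattern, neutrophil and monocyte genes were lower while mast cell, erythroid and platelet genes were higher. A minority of other cells in otherwise ordinary GMPs would leave the granule genes at over 50% of the wild-type level. The median of the 15 primary granule genes kept at most 13.4% (that of Fcnb, at background in the mutant cells), and Mpo, above background in both groups, kept 0.891%, which argues against that. A difference between the sets of arrays that reaches bright genes in general would move ribosomal protein and oxidative phosphorylation genes too. These 88 genes had a median absolute change of 0.145. It was 2.23 for the 74 genes of the primary granule, monocyte, mast cell, erythroid and platelet lists, or 1.69 for 98 genes with the late neutrophil and eosinophil lists added. Quantile normalization within RMA can remove a general shift of bright genes, so the small change decides little. A difference between the sets confined to particular transcripts or to dim genes was not tested. The gates remain open, because the wild-type gate required CD34 and the mutant gate did not, and Cd34 changed by -2.28, which either gate or genotype could give; a population replaced by cells of another lineage and a changed program within GMPs cannot be told apart here, and the genotype itself stays untested.

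In the second pattern, interferon-stimulated genes were higher. Macrophages within the sort would bring their abundant transcripts, yet the highest change among C1qa, C1qb and C1qc was 0.24 on the log2 scale (C1qb, at 7.65 and 7.40), and 0 of 13 macrophage genes rose over 2-fold in limma, 3 of them having passed at smaller changes, against 20 of 23 interferon genes, which argues against macrophages as the source of the RNA. Plasmacytoid dendritic cells, which a lineage-negative, c-Kit-positive gate should remove, were not excluded by their marker Siglech (-0.14), at background in both groups (5.17 and 5.31), although Irf8 (-3.80) and Flt3 (-2.77), which they also express, fell and Bst2 differed by 0.18 (adjusted p = 0.364); interferon made elsewhere in the animal stays open. A different genetic background of the mice remains open: Nnt, which is deleted in part in a substrain of C57BL/6, changed by -3.18 ± 0.08 (SE), so the 2 groups may differ in loci besides those named in the genotype. Whether the interferon genes follow such a difference, the lesions or separate handling cannot be told apart with each group in a single genotype.

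In the third pattern, long runs of neighbouring genes were higher together in the mutant cells, in the gene order of GRCm38.p6 over 8299 genes with a mean value above 7. The run of 354 genes from Ifnz to Agrn, which includes Cdkn2a and Cdkn2b, had a median log2 change of 0.39 and that of 75 genes from Adgrg7 to A630089N07Rik one of 0.34, against -0.06 for the other genes, with borders chosen on the same values. Only Cdkn2a and Cdkn2b were looked up by name, so other genes named in the report may also lie within these runs. Chance order gave a sum of ranks along a chromosome as large as the largest in 0 of 1000 shuffles (6 for the next run and 37 for a further one from Ptpn4 to Cr1l). That further run of 231 genes had a median of 0.26. Its genes were counted among the other genes, and its excess on each array was not taken. A few strongly changed genes would leave the lower quartile in place, and it lay at least 0.406 above that of the other genes. The runs were picked by ranks of these same values, so a raised quartile was largely set by that choice and decides nothing. A candidate explanation is an extra copy of these segments in the mutant cells, which predicts at most 0.585 if expression follows copy number: the excess of the 2 runs over other genes was between 0.322 and 0.5 on each of the 3 mutant arrays. The same arrays set the borders of the runs, so part of this excess comes from that choice. The extra copy remains a hypothesis, since no DNA was measured and regional regulation was not tested.

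Divisions of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. Each of the other 9 puts arrays of both genotypes on both sides, so the genotype difference enters its residual spread and, in part, its contrast, and none is a comparison free of the genotype. Genes changed were 10317 in the real division and at most 0 in limma in the others (11395 against at most 192 at an unadjusted p under 0.05), genes changed over 2-fold 2867 and at most 0, and receptor genes changed 128 and at most 0. In each of these the real division was the 1 with as many. Lists shifted with the preset correlation were 15 in the real division, and 2 of the 10 reached that number. The other joined inv(16)/KitD816Y L-GMP replicates 1 and 3 with wild-type GMP replicate 1 and gave 17 lists with 0 genes changed in limma and 136 at an unadjusted p under 0.05. That contrast holds part of the genotype difference, and the cause of the 17 was not tested.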
